A study of Homo sapiens with 6 samples.

How the data were processed

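Total RNA of HCC-LM3 cells was extracted with TRIzol and made into libraries with the VAHTS Universal V6 kit, per the labels' protocols. There were 3 DMSO and 3 apigenin samples, grouped by their titles. Per the submitters' processing notes, fastp, HISAT2 and HTSeq were used with the GRCh38 (hg38) build, and no versions are given in the sources used here. Whether the counting used strand is not stated. The authors deposited for each sample a table of read counts per gene symbol, not normalized, and a table of FPKM values. The deposited counts are whole numbers for 23059 genes, each with 1 or more reads in some library. The deposited FPKM equal the count divided by a fixed whole-number gene length and by the library total for 100% of genes (relative tolerance 0.0001), so gene lengths were taken from them, with a median of 3289 nucleotides. Of the symbols, 21752 matched a RefSeq gene symbol of GRCh38, from which positions and overlapping genes were taken.

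Totals ranged from 33882145 to 37983636 counts, so that 0 reads in a library allow up to 0.079 to 0.0885 CPM (3 counts). These floors cover counting error only. Mitochondrially encoded genes took 6.47 to 6.95% of counts. Ribosomal protein genes took 3.59, 3.66 and 3.61% in the DMSO and 4, 3.71 and 4.7% in the apigenin libraries. Replicates differed by more than counting noise, with a chi-square over its degrees of freedom of 4.4 to 5.26 between DMSO libraries and 9.23 to 29.6 between apigenin libraries, so that none was a copy of another.

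The groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with TMM factors, the default filter on low counts (15173 genes kept) and Benjamini-Hochberg adjustment over the tested genes at 0.05. The standard error of a log2 fold change is its size over the root of the F statistic. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, over the 32 of 34 lists with 5 or more tested members, and again with an estimated correlation and with fry. The test, the lists, most of the other settings and the rule for named genes were fixed before the data were examined. The rule took, among called genes with a mean of 5 CPM or more and no overlap between the groups, the 10 largest and 10 smallest log2 fold changes. It took up to 4 called members (mean of 1 CPM or more) of each list on vesicles and angiogenesis and of each list called by camera. It added ARF6, RHOA, ROCK1, ROCK2, MYLK, PLD2, TSG101, VEGFA, CYP1A1, HMOX1, CDKN1A and DDIT3. Other genes are said to be named after their values were seen. The values of 4 called genes that the rules above name are not reported here.

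The other settings chosen beforehand were DESeq2 1.42.0, other scaling factors, no filter and a stricter filter (1 CPM in 3 libraries), the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a filter of 0.5 FPKM in 3 libraries, limma on log2(FPKM + 1) without that filter, and each library left out in turn. Fold changes on the FPKM scale understate those of low genes. Settings added after seeing the data removed each library's smooth trend (lowess, span 0.3) on log2 gene length, on GC content, or on both, as offsets. GC content came from the longest GENCODE 29 transcript and was known for 14096 of the 15173 genes.

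The steps were tested on simulated data with the means, totals and dispersions of these libraries and 200 changed genes. The changed genes were drawn only from genes above a minimum mean count. Of 50 genes changed at each size, edgeR recovered 18 at 1.2-fold, 44 at 1.5-fold, 50 at 2-fold and 50 at 4-fold, with 13 calls among unchanged genes. With no change simulated, 1 gene and 0 of the lists were called. Each gene was drawn independently, so the simulations cannot show how correlation between members of a list affects camera. A list of 20 genes moved by 0.3 was called (adjusted p = 1.45e-20, or adjusted p = 0.0313 with an estimated correlation). A simulated slope on length of -0.07, -0.02 and -0.15 in the 3 apigenin libraries, with no gene changed otherwise, led camera to call 2 lists higher, among them the ribosomal proteins (adjusted p = 9.56e-07), and 0 lists once the trend was removed.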

Results

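HCC-LM3 cells, a human hepatocellular carcinoma line with high metastatic potential, were treated with apigenin, a plant flavone, or with DMSO as the control. Total RNA of 3 cultures per group was sequenced, and the labels name the samples biological replicates. The question was how apigenin changes gene expression in these cells, in a study whose title is about microvesicle formation and tumour angiogenesis. Dose and duration are not given in the sources used here. The 3 DMSO libraries held 37173442, 37276429 and 34647650 counts, and the 3 apigenin libraries 33882145, 37983636 and 34011537. Levels are CPM (counts scaled to library size with TMM factors) as mean ± SD of 3 libraries. Log2 fold changes are apigenin over DMSO ± SE, and positions are on GRCh38.

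Among genes with a mean of 5 CPM or more, CYP1A1 and CYP1B1 rose furthest with apigenin. CYP1A1 (chromosome 15, 74719542 to 74725528), a cytochrome P450 switched on by the aryl hydrocarbon receptor, rose 31.8-fold, from 5.09 ± 0.651 to 162 ± 6.3 CPM (log2 fold change 4.99 ± 0.091, n = 3 per group, adjusted p = 1.59e-13). CYP1B1 (chromosome 2, 38067509 to 38076151), another target of that receptor, rose 8.39-fold, from 66.7 ± 3.19 to 559 ± 34.7 CPM (3.07 ± 0.066, adjusted p = 7.72e-13). ALB (chromosome 4, 73404287 to 73421482), which encodes serum albumin, fell from 123 ± 3.3 to 52.9 ± 1.23 CPM (-1.22 ± 0.060, adjusted p = 3.82e-08). SOX9 (chromosome 17, 72121020 to 72126416), a transcription factor of biliary and progenitor cells, fell from 73.9 ± 1.97 to 32.1 ± 0.842 CPM (-1.20 ± 0.066, adjusted p = 1.27e-07).

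Among the 10 named genes with the largest rises, TIPARP, a further receptor target, rose from 38.8 ± 2.25 to 142 ± 8.99 CPM. It overlaps its antisense gene TIPARP-AS1, from which its reads cannot be told apart without strand. MB21D2 rose by 2.12 ± 0.149 on the log2 scale, the adhesion receptor gene ADGRF1 by 1.98 ± 0.143, and BMF, which encodes a cell death activator of the BCL2 family, by 1.36 ± 0.128. The metallothionein genes MT1X and MT2A rose by 1.78 ± 0.189 and 1.64 ± 0.114. The other 2 were the uncharacterised genes LOC112268189 (1.89 ± 0.115) and LOC105378088 (1.55 ± 0.163). Among the 10 with the largest falls were FOSB, an AP-1 transcription factor gene (-1.18 ± 0.093), the tight junction gene CLDN2 (-1.12 ± 0.118), and SERPINA1, which encodes alpha-1 antitrypsin (-1.03 ± 0.086). CLDN2 overlaps RIPPLY1. IGFBP5, which encodes a binding protein of insulin-like growth factors and overlaps IGFBP-AS1, fell from 61.3 ± 1.29 to 31.2 ± 2.71 CPM. DUOX2, which encodes a peroxide-forming oxidase, fell by 1.05 ± 0.185 on the log2 scale, LINC00342 fell by 1.04 ± 0.130, ANKRD36C fell by 1.08 ± 0.193 and the mucin gene MUC5B, which overlaps MUC5B-AS1, fell by 0.97 ± 0.179. ANKRD36C belongs to a family of near-identical copies, so its level is uncertain. The rule for these 20 genes required that the libraries of the groups did not overlap. MUC5B alone of the 20 lost its call when 1 library was left out (-0.88 without DMSO 2, adjusted p = 0.0503, and up to 0.14 over all settings). With the length trend removed MUC5B, of 17911 nucleotides, stood at -0.78.

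**Figure D1:**
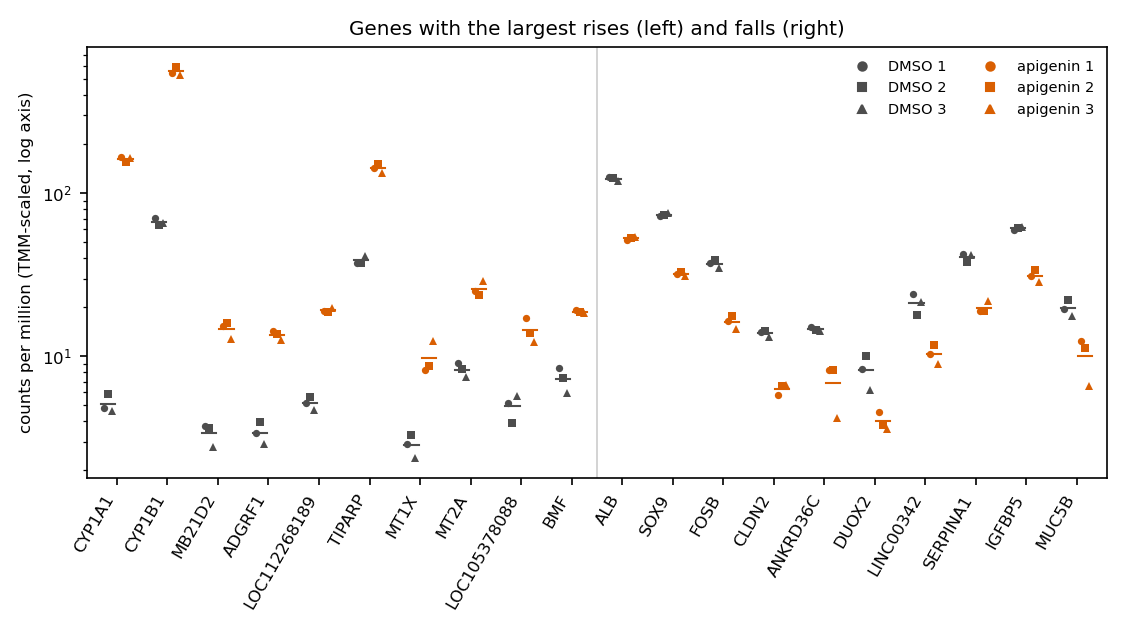
CPM (log axis) of the 10 named genes with the largest rises and the 10 with the largest falls; each point is 1 library, each bar the mean of 3, with DMSO in grey and apigenin in orange. CYP1A1 goes from a mean of 5.09 to 162 and ALB from 123 to 52.9, and by the rule that chose the 20 genes the groups do not overlap.

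Of 15173 genes tested, 419 rose and 641 fell with apigenin at an adjusted p under 0.05, and 39 of the former and 18 of the latter by at least 2-fold. The first principal component, with 33.0% of the variance, separated the groups. DMSO 1, 2 and 3 stood at -19.5, -17.6 and -24.8 and apigenin 1, 2 and 3 at 19.0, 5.0 and 37.9. The apigenin scores kept the order of the slopes on gene length given below, so this axis was not separated from that trend. On log2 CPM, apigenin 2 had a Pearson correlation of 0.9872 with apigenin 1, 0.9858 to 0.9865 with DMSO libraries and 0.9843 with apigenin 3. The p-values set the group difference against the spread within groups, taken over both groups together and moderated across genes. They rest on few samples. That spread was unequal, with a chi-square over its degrees of freedom of 4.4 to 5.26 between DMSO and 9.23 to 29.6 between apigenin libraries. Leaving out DMSO 1, DMSO 2 or DMSO 3 left 103, 140 and 124 genes higher and 157, 179 and 181 lower. Leaving out apigenin 1 left 126 and 184, apigenin 2 gave 1344 and 1546, and apigenin 3 gave 575 and 827. Of the 55 called genes that the rule names, 22, 19 and 20 lost their call without DMSO 1, 2 or 3, 20 without apigenin 1, 0 without apigenin 2 and 2 without apigenin 3, each in an unchanged direction. Among the 22 that passed under each of the 21 settings were the 10 with the largest rises, ALB, SOX9, FOSB, CLDN2, SERPINA1, IGFBP5, LMCD1, HMGCS1, PSMB9 and CDH1.

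The fold changes followed gene length. Across the tested genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.36 with length, and 333 of the 641 genes that fell were in the longest of 5 equal groups by length (7092 nucleotides or more). In the shortest group (up to 1987 nucleotides) 134 genes rose and 15 fell. Relative to the DMSO mean, the slope per doubling of length was -0.071 log2 units in apigenin 1, -0.021 in apigenin 2 and -0.147 in apigenin 3, against 0.001, -0.005 and 0.003 in the DMSO libraries. An exact two-sided permutation test of the 3 slopes against 3 gave p = 0.1, the smallest it can give. With each library's length trend removed, an alternative chosen after seeing the data, 702 genes were higher and 816 lower, which included 348 of the 419 and 525 of the 641.

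**Figure D2:**
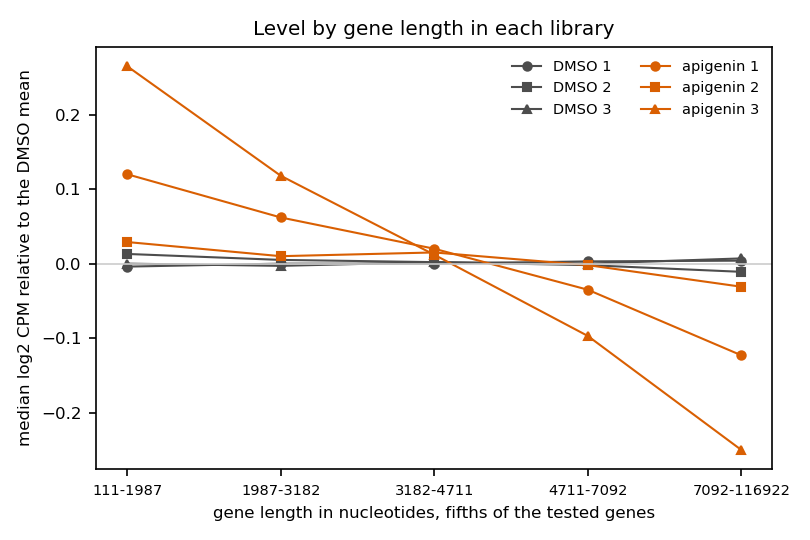
Median log2 CPM of each library relative to the DMSO mean (vertical axis) in 5 equal groups of the tested genes by length in nucleotides (horizontal axis); grey lines are DMSO and orange lines apigenin libraries. Apigenin 3 falls from 0.265 in the shortest group to -0.250 in the longest, apigenin 1 from 0.120 to -0.123 and apigenin 2 from 0.029 to -0.031.

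Most of the tested aryl hydrocarbon receptor targets rose. Of 8 tested members, 5 rose, 1 fell and 2 did not pass (7 higher and 1 lower adjusted over the list alone), and the list was called higher by camera (adjusted p = 6.30e-08, or adjusted p = 0.0624 with an estimated correlation). Beside CYP1A1, CYP1B1 and TIPARP, LMCD1 rose from 40.7 ± 1.34 to 72.5 ± 4 CPM (0.83 ± 0.069), and SLC7A5, an amino acid transporter gene, by 0.76 ± 0.056. UGT1A6 fell by 0.29 on the log2 scale and lost its call without DMSO 1, 2 or 3 or apigenin 1 (adjusted p over all settings of up to 0.148), and it shares its locus with 8 other listed UGT1A genes, so its level is uncertain. SLC7A5 and UGT1A6 were named after their values were seen. With the length trend removed the list kept its call (adjusted p = 7.12e-08, or adjusted p = 0.0621 with an estimated correlation).

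Most tested genes of the metallothionein list, which bind or move zinc, also rose. Of 6 members 5 rose (6 adjusted over the list alone), with camera adjusted p = 6.30e-08 and adjusted p = 0.134 with an estimated correlation. MT1G had 0.414 ± 0.291 CPM with DMSO and 2.69 ± 0.337 with apigenin (2.68 ± 0.462, adjusted p = 0.00393). MT1M, named after its values were seen, had 0 reads in the DMSO libraries and 19, 18 and 19 with apigenin, at least 19.2-fold higher against a floor of 3 counts over the DMSO group. SLC30A1, a zinc exporter gene, rose by 0.22 ± 0.061 and lost its call without DMSO 1, 2 or 3 or apigenin 1 (adjusted p of up to 0.185 over all settings). The tested members are short, with a median of 407 nucleotides. With the length trend removed MT1X stood at 1.54 and MT2A at 1.41, both still called. The list kept its call (camera adjusted p = 3.68e-08, or adjusted p = 0.0998 with an estimated correlation). Metallothionein genes are close copies of one another, so the level of each is uncertain.

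Some genes of sterol and fatty acid synthesis fell. Of 25 cholesterol synthesis and uptake genes, 9 fell and 16 did not pass at the threshold over all genes, and 15 fell when adjusted over the list alone (camera adjusted p = 1.87e-07, or adjusted p = 0.0624 with an estimated correlation). STARD4, a sterol carrier gene, fell from 22.1 ± 0.619 to 14.1 ± 2.8 CPM (-0.65 ± 0.125), and lost its call without DMSO 1 or apigenin 1 (adjusted p of up to 0.152 over all settings). HMGCS1, which encodes an early enzyme of cholesterol synthesis, fell from 64.9 ± 2.27 to 48.6 ± 1.34 CPM (-0.42 ± 0.065). Of 16 fatty acid synthesis genes, 6 fell, 1 rose and 9 did not pass (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.61e-04, or adjusted p = 0.365 with an estimated correlation). On the log2 scale LPIN1 fell by 0.49 ± 0.112, the carboxylase gene ACACA fell by 0.38 ± 0.093, the synthase gene FASN fell by 0.28 ± 0.059 and ACSS2 fell by 0.28 ± 0.078. The member that rose, named after its values were seen, was the regulator gene SREBF1 (0.24 ± 0.063, adjusted p = 0.0357), which overlaps RAI1. With the length trend removed, 15 cholesterol and 9 fatty acid synthesis genes fell. The log2 fold changes of the long genes STARD4, ACACA and FASN shrank to -0.51, -0.23 and -0.17. LPIN1, ACACA, FASN, ACSS2 and SREBF1 each lost their call without DMSO 1, 2 or 3 or apigenin 1, and ACSS2 also without apigenin 3, with adjusted p over all settings of up to 0.183, 0.235, 0.136, 0.221 and 0.183.

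**Figure D3:**
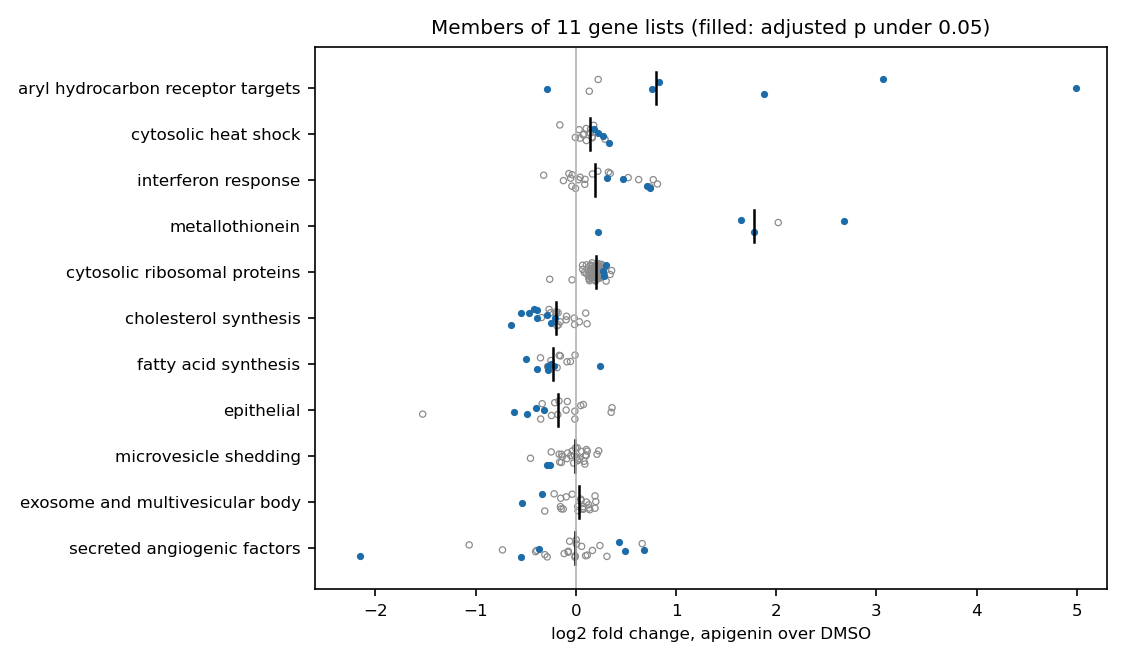
Log2 fold change (horizontal axis) of each tested member of 11 gene lists (rows); filled points passed the test over all genes, open points did not, and bars are medians, with MT1M left out because it had 0 reads with DMSO. CYP1A1 stands at 4.99 among receptor targets, and 9 cholesterol synthesis genes are filled on the left of 0.

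Of 19 epithelial genes, 4 fell and 15 did not pass (6 lower adjusted over the list alone; camera adjusted p = 0.00383, or adjusted p = 0.19 with an estimated correlation). CDH1, which encodes E-cadherin, fell from 29.2 ± 1.65 to 19.1 ± 1.09 CPM (-0.61 ± 0.087, adjusted p = 0.0011). The desmosome gene DSP fell by 0.48 ± 0.086, the protease inhibitor gene SPINT1 by 0.40 ± 0.093 and the keratin gene KRT19 by 0.32 ± 0.071 on the log2 scale. With the length trend removed DSP, of 9697 nucleotides, stood at -0.35, CDH1 at -0.59, SPINT1 at -0.44 and KRT19 at -0.45. All 4 stayed called. SPINT1 lost its call without DMSO 1, 2 or 3, and KRT19 also without apigenin 1 (adjusted p over all settings of up to 0.113 and 0.129).

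Some heat shock and interferon response genes rose. Of 18 cytosolic heat shock genes, 4 rose and 14 did not pass (6 higher adjusted over the list alone; camera adjusted p = 0.00156, or adjusted p = 0.425 with an estimated correlation). These were HSPA1B (0.33 ± 0.061), BAG3 (0.27 ± 0.061), HSPA1A (0.23 ± 0.057) and HSPH1 (0.19 ± 0.053), of which HSPA1A and HSPA1B are near-identical copies and uncertain. All 4 lost their call without DMSO 1, DMSO 3 or apigenin 1, and all but HSPA1B without DMSO 2 (adjusted p over all settings of up to 0.0833, 0.123, 0.184 and 0.206). The median rise of the list was 0.10, 0.07 and 0.18 in apigenin 1, 2 and 3, in the order of the slopes on length. With the length trend removed its median log2 fold change went from 0.15 to 0.08. Camera still called it (adjusted p = 0.0157, or adjusted p = 0.354 with an estimated correlation). Of 24 interferon response genes, 4 rose and 20 did not pass (8 higher adjusted over the list alone; camera adjusted p = 0.00166, or adjusted p = 0.134 with an estimated correlation). IRF1, a transcription factor gene, rose from 20.9 ± 1.46 to 34.8 ± 5.01 CPM, the immunoproteasome gene PSMB9 from 6.36 ± 0.25 to 10.4 ± 0.99, and the antiviral gene OAS1 from 283 ± 7.11 to 351 ± 9.18. ISG15 rose by 0.47 ± 0.115 and was not called with the length trend removed (0.27, adjusted p = 0.0639). It also lost its call without DMSO 1, 2 or 3 or apigenin 1, and OAS1 without DMSO 1 (adjusted p over all settings of up to 0.151 and 0.0534).

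Cytosolic ribosomal protein genes were higher as a list, by little and unevenly. Of 77 genes, 3 rose and 74 did not pass, 35 rose when adjusted over the list alone, and the median log2 fold change was 0.20 (camera adjusted p = 5.54e-09, or adjusted p = 0.638 with an estimated correlation). RPLP1, which overlaps LINC02896, rose by 0.31 ± 0.083 and RPS9 by 0.28 ± 0.079. Both lost their call without DMSO 1, 2 or 3 or apigenin 1 (adjusted p over all settings of up to 0.285 and 0.257). The median rise was 0.15 in apigenin 1, 0.02 in apigenin 2 and 0.42 in apigenin 3, in the order of the slopes on length. In simulated data with slopes on length close to these and no gene changed otherwise, camera also called this list higher (adjusted p = 9.56e-07). With the length trend removed the median was 0.06, RPLP1 stood at 0.16 (adjusted p = 0.024) and RPS9 was not called (adjusted p = 0.0646), while 10 members rose and camera still called the list (adjusted p = 0.0144, or adjusted p = 0.655 with an estimated correlation). The list was not called with that trend removed and apigenin 3 also left out (adjusted p = 0.372), nor by fry (adjusted p = 0.242). Without that removal it was called with any 1 library left out (adjusted p of 2.05e-14 to 7.71e-06).

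Genes of vesicle release were mostly not called. Of 30 genes of microvesicle shedding, 2 fell and 28 did not pass (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.493), and of 24 genes of exosomes and multivesicular bodies, 2 fell and 22 did not pass (2 lower adjusted over the list alone; camera adjusted p = 0.838). The small GTPase gene RHOB fell from 85.1 ± 3.41 to 69.7 ± 3.42 CPM (-0.29 ± 0.065, adjusted p = 0.0186), and ANO6, which encodes a phospholipid scramblase, from 339 ± 1.18 to 283 ± 28.5 CPM (-0.26 ± 0.067, adjusted p = 0.036). The tetraspanin gene CD82 fell by 0.53 ± 0.141 and RAB27B, which acts in vesicle docking, by 0.34 ± 0.084. With the length trend removed RAB27B stood at -0.20 and ANO6 at -0.17, both still called (adjusted p = 0.0273 and 0.0141). Each of these 4 calls was lost without DMSO 1, 2 or 3 or apigenin 1, and that of CD82 also without apigenin 3. Adjusted p over all settings reached 0.12 for RHOB, 0.216 for ANO6, 0.165 for CD82 and 0.223 for RAB27B. Of the genes fixed for this question, ARF6 had a log2 fold change of 0.04 ± 0.054, RHOA of 0.06 ± 0.055, ROCK1 of -0.09 ± 0.085, ROCK2 of -0.13 ± 0.079, PLD2 of -0.14 ± 0.10 and TSG101 of 0.02 ± 0.075. MYLK, which encodes myosin light chain kinase, had -0.45 ± 0.141 (adjusted p = 0.0677). None of these 7 passed the test. MYLK was called in 5 of the 21 other settings (log2 fold change -0.63 to -0.17 and adjusted p from 8.86e-05 to 0.339 over all), and ROCK1 and ROCK2 in 1 each, without apigenin 2 (adjusted p = 0.0366 and 0.0326).

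Secreted angiogenic factors went both ways. Of 27 tested, 3 rose, 3 fell and 21 did not pass (4 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.621). Over all 15173 tested genes 419 rose and 641 fell. Camera tests for a common shift of a list, so it does not address members that move both ways. Fry's test for changes in either direction gave an unadjusted p = 7.86e-06, against 0.0211 for microvesicle shedding and 0.00594 for exosome genes. It asks whether members changed at all, not whether they changed more than other genes. PDGFA rose from 13.3 ± 1.68 to 21.5 ± 1.06 CPM (0.68 ± 0.109, adjusted p = 0.00233), and ADM, which encodes adrenomedullin, by 0.49 ± 0.080. CCN2 fell from 71.6 ± 1.11 to 49 ± 5.4 CPM (-0.55 ± 0.078, adjusted p = 0.0011). The other genes that fell, TGFB1 (-0.37 ± 0.071) and CXCL1 (-2.15 ± 0.511, from 1.09 CPM), were named after their values were seen. Both lost their call without DMSO 2 or 3 or apigenin 1, and CXCL1 also without DMSO 1 or apigenin 3 (adjusted p over all settings of up to 0.0836 and 0.124). VEGFA had 71.3 ± 1.17 CPM with DMSO and 67.7 ± 3.28 with apigenin (-0.08 ± 0.064, adjusted p = 0.508) and did not pass the test.

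Most members of the stress and growth lists did not pass the threshold, against 419 genes higher and 641 lower of all 15173 tested. Camera, which tests for a common shift, called none of these lists on the counts of all 6 libraries. Fry's test for changes in either direction gave unadjusted p from 2.93e-07 for hypoxia and glycolysis to 0.0787 for endoplasmic reticulum chaperones. On log2(FPKM + 1) without a filter camera called NRF2 targets and homologous recombination genes (adjusted p = 0.0486 for each, against 0.638 for each on the counts with an estimated correlation). Genes in this paragraph and the next other than HMOX1, CDKN1A, DDIT3, ADM and CCN2 were named after their values were seen. Of 23 NRF2 targets 4 rose and 1 fell (7 and 4 adjusted over the list alone). The heme oxygenase gene HMOX1 rose by 0.31 ± 0.057 (adjusted p = 0.00554), with OSGIN1, SRXN1 and TXNRD1, while AKR1B10 fell. Of 24 p53 targets, the cytokine gene GDF15 rose by 0.62 ± 0.068 and the death receptor gene TNFRSF10B fell (3 higher and 5 lower adjusted over the list alone). CDKN1A, a cell cycle inhibitor gene, had 0.38 ± 0.110 (adjusted p = 0.0553), and was called in 6 of the 21 other settings (adjusted p of 0.013 to 0.213 over all). Of 25 ATF4 targets 4 rose, SLC7A5, STC2, PHGDH and SLC3A2, and 2 fell, TRIB3 and the glutathione-degrading enzyme gene CHAC1 (-1.12 ± 0.219; 5 and 3 adjusted over the list alone). DDIT3, a stress transcription factor gene, had -0.24 ± 0.097 (adjusted p = 0.139) or, with the length trend removed, -0.39 (adjusted p = 5.51e-04, within 1.09e-05 to 0.338 over all settings). Of 19 endoplasmic reticulum chaperone genes HSPA5 rose and SEL1L fell (1 and 1 adjusted over the list alone). Of 29 hypoxia and glycolysis genes, the glucose transporter gene SLC2A1 rose from 159 to 234 CPM (0.56 ± 0.059), ADM rose and PFKFB3 fell (2 and 2 adjusted over the list alone). Of 40 DNA replication genes FEN1 rose (1 adjusted over the list alone), and fry called that list (adjusted p = 0.0299). Of 41 genes of G2 and mitosis CDC25B rose and the proliferation marker MKI67, CENPF and FOXM1 fell (1 and 3 adjusted over the list alone). MKI67 and CENPF are 13228 and 10410 nucleotides long, and CENPF was not called with the length trend removed (adjusted p = 0.0815). That removal also shrank the log2 fold changes of MKI67 to -0.19, SEL1L to -0.16 and HMOX1 to 0.20, each still called. Of 21 genes of homologous recombination and the Fanconi anaemia pathway FANCD2 fell (2 adjusted over the list alone). Camera's adjusted p ran from 0.115 for homologous recombination, which was called without apigenin 2 (0.0263, within 0.0263 to 0.338 with 1 library left out, against 0.638 with an estimated correlation and all libraries), to 0.978 for p53 targets. Of the called genes in this paragraph, only GDF15, SLC7A5, SLC2A1, ADM and FEN1 kept their call with each single library left out. HMOX1 lost it without DMSO 1, DMSO 3 or apigenin 1, and over all settings the highest adjusted p of the others was 0.26, for AKR1B10.

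Further lists were not called by camera on these counts either, with adjusted p between 0.139 for mesenchymal genes and 0.978 for TGF-beta targets. Of 10 Wnt targets CCND1 rose, and DKK1, a secreted Wnt inhibitor gene, fell by 0.60 ± 0.061 along with RNF43, which was not called with the length trend removed (-0.20, adjusted p = 0.0811). Of 16 mesenchymal genes SNAI2 rose and the fibronectin gene FN1 fell, of 24 lysosome and autophagy genes CTSL rose, and of 10 acute phase genes PIM1 rose. On log2(FPKM + 1) without a filter camera called the lysosome list (adjusted p = 0.0486, against 0.651 on the counts with an estimated correlation). Adjusted over the list alone, the Wnt, mesenchymal, lysosome and acute phase lists gave the same numbers of calls. Fry called the Wnt and mesenchymal lists (adjusted p = 0.0165 and 0.0168). Of 18 TGF-beta targets 2 rose, among them TGIF1, and ID3, TGFB1 and CCN2 fell (4 and 4 adjusted over the list alone). Of 14 drug metabolism genes POR and UGT1A1, which shares its locus with other UGT1A genes, rose and CYP3A5 fell (2 and 3 adjusted over the list alone). Of 13 mitochondrially encoded genes 0 were called by edgeR, also when adjusted over the list alone, 2 were lower at an unadjusted p under 0.05, and DESeq2 called 2 lower. With the length trend removed 9 were lower and camera called the list (adjusted p = 7.69e-05 against 0.671, or adjusted p = 0.431 with an estimated correlation). The median log2 fold change and camera's direction differed in sign for exosome, hypoxia, p53, ATF4, acute phase and G2 and mitosis genes, the last with a median of 0.00 when rounded. Of the called genes in this paragraph, only DKK1, CCN2, UGT1A1 and CYP3A5 kept their call with each single library left out. FN1 and CTSL lost it without DMSO 1 alone, and over all settings the highest adjusted p was 0.197, for CCND1 and FN1.

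Markers of other cell types were few. Of 4 tested endothelial markers edgeR called 0 (2 lower adjusted over the list alone and at an unadjusted p under 0.05, and DESeq2 called 1 lower), with KDR at 55.7 CPM with DMSO and 46.3 with apigenin. Of 3 fibroblast markers LUM rose (1 adjusted over the list alone). Of 5 leukocyte markers ITGAM fell (3 adjusted over the list alone; camera adjusted p = 0.0502, 0.0106 to 0.159 with 1 library left out, and 0.425 with an estimated correlation). The leukocyte list was called lower in 10 of the 21 other settings that tested it. Among these were the replicate block (camera adjusted p = 0.0463) and the length trend removed (0.00515, or 0.177 with an estimated correlation too). LUM and ITGAM lost their call without DMSO 1, 2 or 3 or apigenin 1 (adjusted p over all settings of up to 0.146 and 0.164).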

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

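The settings that remove a length or GC trend were chosen only after the results were seen; the others were planned. Against 419 genes higher and 641 lower, DESeq2 gave 727 and 973, and no low-count filter 865 and 1096 (67 and 36 at 2-fold or more, against 39 and 18). On log2(FPKM + 1), 303 were lower and 15 and 3 passed 2-fold. On log2(FPKM + 0.1), 289 were lower. Without a filter, log2(FPKM + 1) gave 78 and 60 (11 and 3). Leaving out 1 library moved the counts between 103 and 1344 higher, 157 and 1546 lower, 23 and 78 higher and 9 and 66 lower by 2-fold, lowest without DMSO replicate 1 and highest without apigenin replicate 2. With the length trend removed 702 were higher, with length and GC 720, with length and the replicate block 828 (36 lower by 2-fold), and with length and apigenin 3 left out 651 (32 lower by 2-fold). The causes were not tested. The replicate block alone gave 455 higher and 776 lower. The deviations of same-numbered libraries correlated at -0.017, -0.019 and -0.048, which gave no sign of pairing by number. With 3 libraries per group this cannot exclude a pairing, and the labels do not state one. Against 5 lists higher and 3 lower, 5 were lower on log2(FPKM + 1), 8 without its filter, 5 with the GC trend removed, 7 by fry, and 6 with the length trend removed, also with GC, with the block or with apigenin 3 left out. Leaving out 1 library gave 3 to 6 lists lower. With an estimated correlation camera called 0 lists higher and 0 lower (3 and 2 at an unadjusted p under 0.05), and with the length trend removed too again 0 and 0 (3 and 4). The other scaling factors, the stricter filter and the GC trend kept all 4 gene counts within 1.5 times. Over 144 named genes and 21 alternatives, 2482 of 3020 values kept direction and side of the threshold, 489 lost their call, 28 gained one and 21 reversed. Most losses came without DMSO 1, 2 or 3 (74, 65 and 67 genes) or apigenin 1 (63). Reversals were of uncalled genes but for TF, at 0.004 with the length trend and 0.006 with both trends removed. In the order length trend, length and GC, length and block, length without apigenin 3, RHOA stood at -0.028, -0.029, -0.028 and -0.030, ROCK1 at 0.037, 0.043, 0.035 and 0.080, ROCK2 at 0.005, 0.011, 0.005 and 0.035, and TSG101 at -0.098, -0.086, -0.097 and -0.105. Leaving out 1 library, ROCK1 ranged from -0.205 to 0.005 (without apigenin 3) and TSG101 from -0.045 (without apigenin 3) to 0.065, with -0.030 without DMSO 2. At these depths the test recovered 18 of 50 simulated 1.2-fold and 44 of 50 simulated 1.5-fold changes, so that changes of these sizes or smaller can be missed. The simulated changes were in genes above a minimum mean count, and recovery in genes with fewer counts was not tested.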

Other observations

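The tests of explanations for the length pattern, the receptor targets and the cholesterol synthesis genes were chosen only after the results were seen, while the count over splits of the libraries and a test on myosin genes were written before theirs. The myosin test, and a test of GC content on the length pattern, were set aside after their results were known to limit how many patterns and explanations are weighed, and their values are given below without weighing. Genes typical of hepatocytes shifted in both directions: 5 of 25 fell and 2 rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.0831, or 0.0157 with the length trend removed, within 0.0177 to 0.428 with 1 library left out; with an estimated correlation 0.638, or 0.316 with the trend removed). Beside ALB and SERPINA1, the apolipoprotein gene APOB fell by 0.75 ± 0.122 on the log2 scale and the transcription factor gene FOXA1 by 0.45 ± 0.063, while CEBPA, another liver transcription factor gene, rose by 0.39 ± 0.074 and TAT, a tyrosine-degrading enzyme gene, by 0.73 ± 0.169. The fifth gene that fell was TF (-0.24 ± 0.059), which stood at 0.004 with the length trend removed. With that trend removed APOB, of 14121 nucleotides, stood at -0.58. CEBPA lost its call without DMSO 1 or 3, and TAT and TF without DMSO 1, 2 or 3 or apigenin 1 (adjusted p over all settings of up to 0.109, 0.143 and 0.984). Fry called the list (adjusted p = 0.0269). Genes in this and the next paragraph other than ALB, SERPINA1, FOSB and CCN2 were named after their values were seen.

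Immediate early genes parted. Of 23 genes of MAPK response and feedback, 3 rose and 3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.204, or 0.0486 on log2(FPKM + 1) without a filter, and 0.425 with an estimated correlation; fry adjusted p = 0.00763). Beside FOSB, FOS fell by 0.48 ± 0.060 and EGR1 by 0.46 ± 0.056 on the log2 scale, while EGR2 rose by 1.54 ± 0.273, FOSL1 by 0.54 ± 0.064 and CCND1, which encodes cyclin D1, by 0.22 ± 0.057. Of 20 NF-kappaB targets 3 rose, IER3 (0.85 ± 0.094), TNFAIP2 (0.50 ± 0.061) and IL1B (0.95 ± 0.198), and 1, CXCL1, fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.0732, or 0.0371 with the stricter filter, and 0.365 with an estimated correlation; fry adjusted p = 0.00458). Of 20 YAP and TAZ targets 5 fell and 15 did not pass (8 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0697, or 0.00495 without apigenin 2, 0.0337 and 0.0481 on log2(FPKM + 1) and log2(FPKM + 0.1), 0.0486 on the former without a filter and 0.0455 with the GC trend removed, within 0.00495 to 0.246 with 1 library left out, and 0.638 with an estimated correlation). These were CCN2, IGFBP3, DOCK5, CRIM1 and NT5E, of which CRIM1 was not called with the length trend removed (-0.11, adjusted p = 0.177). With 1 library left out, IGFBP3 and ERBB3 lost their call without DMSO 1, and CCND1, IL1B, CXCL1, DOCK5, CRIM1, NT5E, CITED2 and FOXO3 without more than 1 of the libraries (adjusted p over all settings of up to 0.294, for FOXO3). Of 20 FOXO targets KLF6, ERBB3, TRIB1 and CITED2 fell, and FOXO3, at 0.31 and 0.49 with the length trend removed, and IGFBP1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.111, or 0.0482 without apigenin 2 and 0.0486 on log2(FPKM + 1) without a filter, within 0.0482 to 0.338 with 1 library left out, and 0.638 with an estimated correlation).

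Of 17 tested genes with a myosin (MYO) symbol, a family looked at after the data were seen along with 7 others, 7 fell and 10 did not pass. These were MYO5A (-0.53 ± 0.095), MYO9A, MYO6, MYO5C, MYO18A, MYO1C and MYO1A, and all 7 were lower also with the length trend removed, MYO6 and MYO18A at -0.22 each against -0.37 and -0.36 (camera adjusted p = 7.93e-06, or 0.00129 with the trend removed; with an estimated correlation adjusted p = 0.436 and 0.285). With the trend removed MYO5A stood at -0.365, and MYO10 was called higher (0.46, adjusted p = 0.00136). Camera called 6 of the 7 other families, none of them with an estimated correlation (adjusted p of 0.436 to 0.45). With the trend removed it called only ARHGEF genes among them, of which 4 of 25 fell (adjusted p = 8.60e-04, or 0.0369 with the trend removed and 0.285 with an estimated correlation too). Only MYO6 and MYO5C kept their call with each single library left out, MYO5A lost it without apigenin 1, and over all settings the highest adjusted p was 0.218, for MYO18A.

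Long genes were lower and short genes higher in the apigenin libraries, and the longest of 5 length groups held 52.0% of the lower calls (48.8% with the GC trend removed and 28.4% with the length trend removed). A loss of long transcripts, or of their ends, in single libraries may account for part of the pattern: the 3 apigenin slopes spread 15.9 times as widely as the 3 DMSO slopes. A response to apigenin in every culture may also account for part, since the highest apigenin slope lay 0.016 below the lowest DMSO slope, by more than the DMSO range of 0.008. Apigenin 1 and 3, with the steepest slopes, had the lowest totals of the 6, but the totals did not order as the slopes did. DMSO 3, with 34647650 counts, had a slope of 0.003, and apigenin 3, with 34011537, one of -0.147. Apigenin 1 had fewer counts, 33882145, but a slope of -0.071. Apigenin 2 had the highest total and a slope below every DMSO library. The slope of the shallowest DMSO library lay 0.005 above the mean of the other DMSO libraries. This lay within the DMSO range and could not decide on depth. With 3 libraries per group, loss in single libraries and a response in every culture were not separated.

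The rise of aryl hydrocarbon receptor targets was too large for the length trend to carry. The median log2 fold change of the length groups ran only from 0.14 in the shortest to -0.13 in the longest. Removing the trend could thus hardly move the median of the 5 members that rose. That median was 1.88 before and 1.88 after (0.80 and 0.89 over all 8 tested). The rise was not carried by 1 library, since the median rise of all 8 in the lowest apigenin library was 94.0% of that in the highest. A candidate explanation is that apigenin, or a product of it in these cells, activates the receptor. This is a hypothesis from the data it was found in, and no dose or receptor-deficient cells were compared.

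The fall of cholesterol synthesis genes was not carried by the length trend, since their median log2 fold change was -0.20 before and -0.22 after its removal. Their median length, 3293 nucleotides, lay in the middle length group, whose median log2 fold change was 0.01. Of these genes 9 were called lower before and 15 after, but lower calls over all genes also rose, from 641 to 816. The fall was not carried by 1 apigenin library, since the highest camera adjusted p with 1 of them left out was 1.35e-04. These calls rest on the preset correlation (adjusted p = 0.0624 with an estimated one, and 0.0559 with the length trend removed too). Lower activity of the sterol-sensing transcription factors in treated cells may account for it, a hypothesis for which no sterol level or protein was measured here. A difference in cell density or medium between the groups was not tested.

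Of the 10 splits of the 6 libraries into 3 and 3, the labelled one alone (1 split) gave 1060 called genes by edgeR, and the highest of the others gave 0 (219 to 1084 genes at an unadjusted p under 0.05, against 3697). With 10 splits the share cannot fall under 0.05. Each of the other splits mixes both treatments within its groups, so that a treatment difference adds to the spread within groups and lowers the calls. Their counts thus do not show what chance alone would give.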
